A study of Homo sapiens with 24 samples.

How the data were processed

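LNCaP cells were treated for 72 h with 2 µM SP-2509 or mock, or transfected for 6 h with siRNA and grown for 96 h, per the labels' protocols. Each ChIP used 5 µg of antibody, 4 replicate ChIPs were pooled per sample, the input was 1%, and libraries were amplified for 15 PCR cycles at about 250 bp, per the labels' protocols. The antibody label names H4 for the lysine 4 mark, while the samples are named H3K4me2, and the sample names were followed. The labels do not say that the 2 libraries of a group came from separate cultures, so the spread between them can be technical. Whether the authors' p-values use that spread is not known, since their test is not named. The Fisher's exact tests here count regions or genes and do not measure it.

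Reads were handled with Bowtie2 and bedtools on hg19, per the submitters' processing notes, which give no versions. The 4 tables have the layout of diffReps, a sliding-window tool for differential ChIP-seq regions, per the file headers, and its version, test and settings are not given in the sources used here. Each table compares 1 treatment with its own control for 1 mark. The signal of a region, as the authors deposited it, is the mean normalised read number of a group, with the 2 library values kept beside it. The deposited enrichment is a linear ratio over a background, and the sources used here do not say whether that background is the input. The authors deposited a log2 ratio of the group means per region, and a p-value and adjusted p-value for the region and its best window. Every listed region has a best-window p-value of at most 9.99e-05, as tested on the deposited values, so weaker windows are not in the tables. The input libraries have no values of their own there and were not analysed here.

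Within a library the deposited values were whole multiples of 1 step, the factor that scales it to the others, in 100% of regions within 0.006. The steps were 1.59 and 0.757 for SP-2509 and 0.621 and 1.30 for mock in the H3K4me2 table, and 1.12 and 1.50 against 0.710 and 0.823 in the H3K9me2 table. They were 1.44 and 0.972 for siLSD1 and 0.813 and 0.867 for siLUC in the H3K4me2 table, and 0.937 and 1.10 against 1.04 and 0.930 in the H3K9me2 table. Dividing by the step gave the reads per region. The sums over called regions are not the depth of the libraries, and tables were scaled separately, so no level was compared between them. Exact intervals cover the counting of regions or reads only.

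From the library values the group mean, SD, log2 ratio of means and its delta-method SE were computed. The adjusted p was taken from the authors' deposited table, and no second test was run on single regions, because the regions had been selected by the authors' test on these same libraries. All 2 by 2 values were separated, with both treated libraries on the same side of both controls, in 99.9% of SP-2509 H3K4me2 regions and in 99.9% of knockdown H3K4me2 regions, and in 100% of both H3K9me2 sets.

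Gene and position columns came from the deposited annotation, which names promoter classes and gene bodies but not exons or introns. The names were compared with a RefSeq gene table of GRCh38.p14, used for names only. On the autosomes 14955 of 15030 gene-annotated regions (99.5%) carried a gene of their own chromosome. On chromosome X all 181 gene-annotated regions carried genes of chromosome 20, and on Y all 12 carried genes of chromosome 21. The gene and position columns of the 875 X and 114 Y regions were therefore left out, and X-linked list members (KDM5C, KDM6A, PHF8 and SUV39H1 among them) were not assessed.

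The comparisons, tests, 14 gene lists and naming rule were fixed before the data were examined. The rule took, among regions in a gene with an adjusted p of at most 0.01 and a larger group mean at or above the table's median, 1 region per gene and the 10 largest rises and falls. To these it added KDM1A, up to 4 genes per list with the largest absolute log2 ratio, and up to 5 overlaps with the lowest larger adjusted p. List genes and overlaps needed no minimum mean, so some changed more than the 10 largest rises or falls, at weaker signal. Further list members named in the text to complete a small group were chosen after their values were seen. Some list members that the rule takes are not reported here. A gene's direction was that of its region with the lowest adjusted p. Lists with at least 3 genes with a region were tested by two-sided Fisher's exact test against all other genes with a called region, with Benjamini-Hochberg adjustment over the lists of a comparison. A count adjusted over the list alone could not be formed, because genes without a called region carry no p-value. Of the 161 list genes of the SP-2509 H3K4me2 comparison, EPCAM and RCOR3 had an adjusted p above 0.05, and C1orf116 and IFIT1 moved by less than 2 SE.

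A promoter region had its centre within 2 kb of a transcription start. Overlaps needed 1 bp and were set against 1000 circular shifts within each chromosome with a fixed seed. Regions are neighbours on the genome and not independent, so p-values over regions are smaller than they should be. Alternatives were adjusted p limits of 0.01 and 0.001, an absolute log2 ratio of at least 1, a minimum mean, autosomes only, merging within 1 kb, directions from the enrichment or from unscaled reads, base pairs in place of regions, promoters within 1 or 5 kb, 50% overlap, random placement, and each library left out. An adjusted p limit of 0.05, the deposited X and Y annotation, and the alternatives for the difference in direction were added after seeing the data. The promoter test at matched enrichment was also added after seeing the data, and its bins of 0.25 log2 units replaced 20 equal-sized bins after their values had been seen. The treated enrichment of lost and gained regions was compared over all pairs of them, also after seeing the data, with a 95% interval from 1000 draws of whole chromosomes with replacement.

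The routines were tested on simulated data. In the SP-2509 H3K4me2 regions (17884) all 7 planted steps and all 200 planted shared regions were recovered. Of 20 independent placements of the knockdown regions 1 had a permutation p of at most 0.05. A planted promoter odds ratio of 3 at matched enrichment came back as a median of 2.89 over 20 draws in the SP-2509 H3K4me2 regions and 2.80 in the knockdown ones. The simulated directions followed control enrichment less sharply than the real ones, and no uniform drop in immunoprecipitation was simulated. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.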

Results

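Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of promoters and enhancers, and at lysine 9 (H3K9me2), a mark of silent chromatin, was mapped by ChIP-seq in LNCaP cells, an androgen-sensitive human prostate cancer line. LSD1 (gene KDM1A) is a demethylase of H3K4me1 and H3K4me2 that has also been reported to act on H3K9. It was depleted with a siRNA (siLSD1) against a luciferase siRNA (siLUC), or inhibited with SP-2509 at 2 µM for 72 h against a mock treatment. The design asked where each mark changed when LSD1 was removed or blocked. The 24 libraries fell into 12 groups of 2, of which 8 groups were ChIPs and the rest were inputs. Inside the called regions, the H3K4me2 libraries of the SP-2509 comparison held 1250964 to 3715058 reads and those of the knockdown comparison 168031 to 299465 reads. The H3K9me2 libraries held 40824 to 72140 reads in the SP-2509 regions and 1378 to 1869 reads in the knockdown regions. The median region had 52 to 117 reads per library for H3K4me2 and 14 to 26 for H3K9me2 in the SP-2509 comparison, against 26 to 44 and 22 to 34 in the knockdown comparison. Positions are hg19, and the values are normalised reads per region with the log2 ratio of the group means.

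After SP-2509, called H3K4me2 regions at promoters were mostly lower and those elsewhere mostly higher. A uniform drop in immunoprecipitation efficiency may give this pattern and was not excluded. By the naming rule, the largest falls were at AADAT, an aminotransferase of the kynurenine pathway (log2 ratio -1.62 ± 0.59, SE, n = 2 libraries per group, as for all log2 ratios here), NCOA2, a coactivator of steroid receptors (-1.53 ± 0.47), and PLD1, a phospholipase (-1.42 ± 0.41). The promoters of ARID4A, CHRAC1, PCCA, SLC35E1, C21orf59, TMCO3 and LOC100125556 fell by 1.36 to 1.42 on the log2 scale. The largest rises were at SPRR1A, a protein of the cornified envelope of keratinocytes (2.45 ± 0.32), at CCDC60 (2.43 ± 0.25), and at DLGAP1, a postsynaptic scaffold (2.40 ± 0.37). C9orf30-TMEFF1, CALCR, PPP2CB, ZNF655, HPSE2, the drug efflux pump ABCB1 and the siderophore-binding protein LCN2 rose by 2.14 to 2.34.

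The SPRR1A region lay in the proximal promoter on chromosome 1 from 152955401 to 152957300, where the normalised reads averaged 139 ± 1.80 after SP-2509 and 25.6 ± 8.06 in mock (SD, n = 2). The LCN2 region, also a proximal promoter, spanned 130910301 to 130912800 on chromosome 9, with 218 ± 24.9 against 49.5 ± 16.5 (SD, n = 2). The AADAT region was in the gene body on chromosome 4 from 171004501 to 171005800, with 34.4 ± 18.7 against 106 ± 20.2 (SD, n = 2). The promoter of KDM1A itself, on chromosome 1 from 23345401 to 23346900, fell from 167 ± 4.21 in mock to 92.0 ± 11.1 (SD, n = 2), a log2 ratio of -0.86 ± 0.13. In the authors' deposited table the adjusted p of the 10 largest rises ranged from 4.36e-09 to 1.13e-08, that of the 10 largest falls from 2.24e-06 to 0.00214, and that of KDM1A was 1.02e-07.

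**Figure D1:**
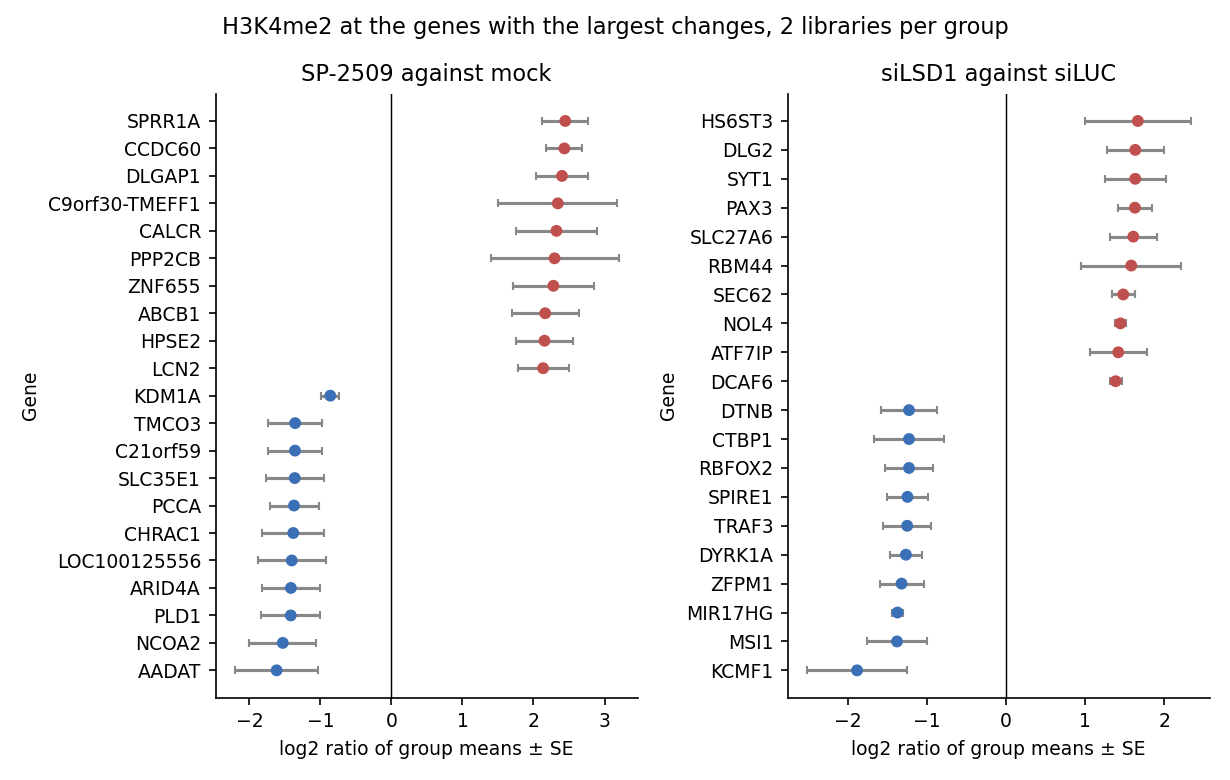
Log2 ratio of H3K4me2 group means (x axis) at the genes with the 10 largest rises and the 10 largest falls by the fixed rule, and at KDM1A where it had a called region (left panel). Bars are the SE from 2 libraries per group, and every bar stays clear of 0, from KCMF1 at -1.88 to SPRR1A at 2.45.

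Genes of histone lysine methyltransferases and demethylases with a called region were mostly lower in H3K4me2 under SP-2509, a call that depended on which regions were used. Of the 40 listed genes 21 had a called region, of which 18 fell and 3 rose by the region with the lowest adjusted p, while 46.7% of the other genes with a region rose (Fisher's exact test, p = 0.00335, adjusted p = 0.0470 over 14 lists). KDM3B (-1.27 ± 0.42) and KDM5B (-1.25 ± 0.28), demethylases of H3K9 and H3K4, fell at their promoters, as did SUV39H2, an H3K9 methyltransferase (-1.20 ± 0.29). The genes that rose were MLL3 (1.54 ± 0.60), JHDM1D (1.37 ± 0.28) and EZH2, the catalytic subunit of PRC2 (0.84 ± 0.10), although 1 of 3 MLL3 regions and 1 of 2 EZH2 regions was higher and the rest were lower. Over all genes with a region in this comparison, 1086 of 7410 had regions going both ways. The odds ratio for a rise was 0.191, without matching on control enrichment, which direction closely followed. With promoter regions alone, where 1 of 14 listed genes and 24.6% of the other genes rose, the odds ratio was 0.236 and the adjusted p of the exact test 0.843. With regions at an adjusted p of at most 0.001 they were 0.217 and 0.150. Genes of the LSD1 complex went both ways, with 5 higher and 7 lower: GFI1B (1.19 ± 0.36), ZEB1 (1.18 ± 0.37) and PHF21A (1.13 ± 0.22) rose, and ZMYM2 (-0.99 ± 0.24) fell (adjusted p = 0.841, Fisher's exact test).

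**Figure D2:**
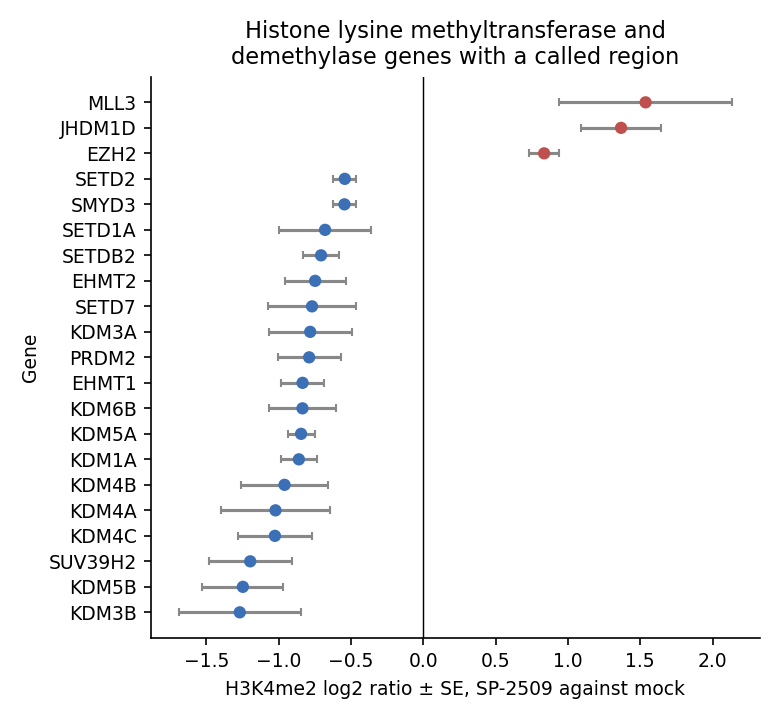
Log2 ratio of H3K4me2 group means after SP-2509 against mock (x axis) at the 21 methyltransferase and demethylase genes with a called region, each at its region with the lowest adjusted p. Bars are the SE from 2 libraries per group, with 18 genes below 0 and 3 (MLL3, JHDM1D and EZH2) above it.

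None of the other 12 lists passed the test in this comparison with all regions. Neuronal and neuroendocrine genes had 10 higher and 3 lower, among them CELF4 (1.75 ± 0.24), SYT1 (1.26 ± 0.22) and INSM1 (1.17 ± 0.24) on the higher side, with p = 0.0472 and an adjusted p of 0.258 by Fisher's exact test. With promoter regions alone 7 of 8 neuronal genes rose against 24.4% of the other genes, and this list passed, with an adjusted p of 0.00396 over 12 lists in the exact test. It also passed among genes whose regions all went one way, with 10 of 12 higher (adjusted p = 0.0373, exact test). The stress genes passed there in the other direction, with 2 of 17 higher against 44.6% of the other genes (adjusted p = 0.0373, exact test). The list tests were not matched on control enrichment, which promoter direction followed. At an enrichment of 1 to 2 in mock, 279 promoter regions rose and 0 fell, and at 16 and above 8 rose and 1640 fell. A list may thus pass through how strongly its promoters were marked in mock, which was not tested. Basal and mesenchymal genes had 6 higher, including TGFBI (1.20 ± 0.08), ZEB2 (1.18 ± 0.39) and the N-cadherin gene CDH2 (1.14 ± 0.17), and 1 lower, VIM (-1.03 ± 0.19), again with an adjusted p of 0.258 in the exact test. Of the androgen-induced genes 23 had a region, 7 higher and 16 lower: INPP4B (1.89 ± 0.39, 3 of 5 regions higher) and SORD (1.52 ± 0.14) rose, and EAF2 (-1.20 ± 0.36) and ACSL3 (-1.06 ± 0.10) fell (exact test, adjusted p = 0.404). Androgen-repressed genes had 3 higher, with CDH11 (1.78 ± 0.23), the receptor tyrosine kinase MET (1.05 ± 0.40) and PEG3 (0.61 ± 0.15), and 2 lower, NFIB (-0.87 ± 0.15, though 4 of 7 regions were higher) and OPRK1 (-0.61 ± 0.16).

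Prostate luminal genes had 5 higher and 3 lower. The pioneer factor FOXA1 (1.00 ± 0.18) and FOLH1, which encodes prostate-specific membrane antigen (0.97 ± 0.08), rose in their gene bodies, and ELF3 (1.03 ± 0.29) and HOXB13 (0.92 ± 0.23) rose more than 1 kb from their transcription starts. EPCAM in this list and RCOR3 in the LSD1 complex were lower by direction only, with adjusted p values of 0.426 and 0.352 in the authors' deposited table. Cell cycle genes had 4 higher, including MCM4 (1.42 ± 0.15), KIF23 (1.21 ± 0.15) and TPX2 (1.00 ± 0.12), and 5 lower, including PCNA (-0.87 ± 0.14), ANLN (-0.75 ± 0.19) and DLGAP5 (-0.75 ± 0.33). Stress genes of the endoplasmic reticulum and of oxidation had 7 higher, such as PPP1R15A (1.53 ± 0.26) and SESN2 (1.35 ± 0.30), and 17 lower, such as VEGFA (-1.16 ± 0.26) and TRIB3 (-1.07 ± 0.16), with an adjusted p of 0.358 in Fisher's exact test. PPP1R15A, SESN2 and TRIB3 each had 1 of 2 regions higher and the other lower. The p53 targets had 6 higher, with XPC (1.85 ± 0.56), DDB2 (1.36 ± 0.26) and BBC3 (1.25 ± 0.35, 1 of 2 regions higher), and 10 lower. Cholesterol synthesis genes had 2 higher, with HMGCS1 at 1.19 ± 0.08, and 6 lower, with MVD at -1.02 ± 0.28. Interferon response genes had 3 higher, with IFIT3 at 1.40 ± 0.45 and OAS2 at 0.85 ± 0.08, and 5 lower, with HLA-C at -0.99 ± 0.27 and B2M at -0.93 ± 0.24. HOX genes had 5 higher, with HOXD11 at 1.17 ± 0.20, HOXD8 at 1.13 ± 0.26 and HOXB8 at 1.12 ± 0.32, and 2 lower, HOXC13 at -1.08 ± 0.34 and HOXC12 at -0.80 ± 0.07. Housekeeping genes had 1 higher and 5 lower, with SDHA at -1.03 ± 0.27 and PPIA at -0.80 ± 0.13.

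The authors' deposited table listed 17884 H3K4me2 regions for SP-2509, of which 10711 (59.9%, exact 95% interval 59.2 to 60.6) were higher and 7173 lower. Within 2 kb of a transcription start 1236 of 4845 regions rose (25.5%), against 9132 of 12439 elsewhere (73.4%), an odds ratio of 0.124 whose p in Fisher's exact test was too small for double precision. The lost regions were strongly marked in mock, with a median enrichment of 11.3 against 1.68 in the gained regions, and among regions matched on it the odds ratio for a rise at promoters was 3.44 (95% interval 2.92 to 4.06), against 1.35 (1.20 to 1.52) when matched on the mean enrichment of both groups. Among the more strongly covered regions, those at or above the table's median mean, 37.6% were higher, so the majority direction turned with that choice. A region of weak control signal has little to lose, which limits what the direction of weak regions can show.

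After SP-2509, H3K9me2 was higher at 2783 of the 2790 regions called for that mark (99.7%, exact 95% interval 99.5 to 99.9). Library scaling and a difference in immunoprecipitation were not excluded as sources of these rises. The largest rises by the fixed rule were in the gene bodies of the phosphoglucomutase gene PGM1 (2.05 ± 0.12), of ENO4 (1.99 ± 0.50) and of RUNX1, a transcription factor of blood development (1.93 ± 0.47). DYSF, ESPNL, GTF2IRD1, ANKH, AIPL1, C1orf111 and COL6A5 rose by 1.78 to 1.89. In PGM1 the region on chromosome 1 from 64082501 to 64083500 averaged 33.0 ± 2.18 normalised reads after SP-2509 and 7.97 ± 0.785 in mock (SD, n = 2). In RUNX1 the region on chromosome 21 from 36309101 to 36310500 averaged 31.3 ± 4.56 against 8.19 ± 3.55 (SD, n = 2). The authors' deposited table gave the 10 largest rises adjusted p values from 6.45e-05 to 0.000419. No fall at a gene passed the naming rule.

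Each listed gene with an H3K9me2 region under SP-2509 was higher. The 7 androgen-induced genes included HERC3 (2.02 ± 0.99), the kinase gene SGK1 (1.79 ± 0.22), TMPRSS2, the protease gene fused to ERG in many prostate cancers (1.57 ± 0.44), and LRIG1 (1.54 ± 0.26), all in gene bodies. The 4 methylation enzymes were KDM4C, an H3K9 demethylase (1.78 ± 0.09), EHMT1, an H3K9 methyltransferase (1.73 ± 0.16), SMYD3 (1.49 ± 0.12) and PHF2 (1.27 ± 0.37). The 3 neuronal genes were SYT1 (2.32 ± 0.47), CHGA (1.35 ± 0.39) and CELF4 (1.34 ± 0.30). The androgen-repressed genes ST7 (1.60 ± 0.56) and AKR1C3 (1.32 ± 0.16), the basal and mesenchymal genes FN1 (1.36 ± 0.17) and ZEB1 (1.31 ± 0.21), and the LSD1 complex genes PHF21A (1.45 ± 0.05) and ZEB1 were higher too. Single genes of 4 further lists rose: CCNE1 (1.46 ± 0.17) of the cell cycle, VEGFA (1.30 ± 0.20) of the stress genes, IFI27 (1.42 ± 0.31) of the interferon response and SESN1 (1.68 ± 0.29) of the p53 targets. Luminal, cholesterol, HOX and housekeeping genes had 0 regions.

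None of the 3 lists large enough to test stood apart, since nearly all genes with an H3K9me2 region were higher (Fisher's exact test, adjusted p = 1 for each). All 96 regions within 2 kb of a transcription start and 2448 of 2453 elsewhere rose (exact test, p = 1). The gained regions were at background level in mock, with a median enrichment of 0.78, and reached 2.29 after SP-2509, with 14 reads in the median region of each mock library. At an adjusted p of at most 0.001 the authors' deposited table kept 364 regions, all higher.

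After LSD1 knockdown, called H3K4me2 regions were mostly lower at promoters and mostly higher in gene bodies and intergenic DNA. Here too a uniform drop in immunoprecipitation efficiency was not excluded. By the naming rule, the largest falls were at KCMF1, a ubiquitin ligase gene (-1.88 ± 0.63), at MSI1, an RNA-binding protein of neural stem cells (-1.38 ± 0.38), and at MIR17HG, the host gene of the miR-17-92 cluster (-1.37 ± 0.07). ZFPM1, DYRK1A, TRAF3, SPIRE1, RBFOX2, DTNB and the corepressor gene CTBP1 fell by 1.23 to 1.32 on the log2 scale, each at its promoter. The largest rises lay in the bodies of HS6ST3 (1.67 ± 0.67), of DLG2, a postsynaptic scaffold (1.63 ± 0.36), of SYT1, a calcium sensor of synaptic vesicles (1.63 ± 0.39), and of the transcription factor gene PAX3 (1.63 ± 0.22). SLC27A6, RBM44, SEC62, NOL4, ATF7IP and DCAF6 rose by 1.39 to 1.61.

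The MIR17HG region on chromosome 13 from 92000201 to 92001600 averaged 18.6 ± 0.198 normalised reads after knockdown and 48.2 ± 3.12 with siLUC (SD, n = 2). The NOL4 region on chromosome 18 from 31486401 to 31488800 averaged 84.6 ± 5.47 against 31.1 ± 0.247 (SD, n = 2). The authors' deposited table gave adjusted p values from 6.50e-05 to 0.00966 for the 10 largest falls and from 1.34e-07 to 0.00943 for the 10 largest rises. KDM1A had no called region in this comparison, and the marks do not measure its transcript or protein, so the depletion itself was not checked here.

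No gene list passed the test after knockdown, where the smallest adjusted p over 8 lists was 0.707 in Fisher's exact test. The 4 genes of the LSD1 complex with a region were all lower, with CTBP1 at -1.23 ± 0.44, CTBP2 at -0.94 ± 0.14, ZMYM2 at -0.93 ± 0.12 and KIAA0182 (now GSE1) at -0.73 ± 0.07. Of the methylation enzymes 5 were lower, among them WHSC1 (now NSD2, -1.35 ± 0.15), PRDM2 (-0.87 ± 0.14) and SUV39H2 (-0.81 ± 0.19), and 2 higher, SMYD3 (1.13 ± 0.28) and MLL3 (0.29 ± 0.08). Androgen-induced genes had 4 higher, led by INPP4B (2.77 ± 0.49) and ABCC4 (1.33 ± 0.05), and 9 lower, including PMEPA1 (-0.89 ± 0.19), KLK4 (-0.88 ± 0.18) and TMPRSS2 (-0.67 ± 0.01). The INPP4B region rose more than the largest rises by the naming rule, which left it out for a group mean below the median. The luminal regulators GATA2 (-0.55 ± 0.07) and SPDEF (-0.62 ± 0.10) were lower.

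Among cell cycle genes after knockdown, the kinetochore genes NUF2 (1.36 ± 0.11), NDC80 (1.12 ± 0.23) and CENPE (0.90 ± 0.08) were higher and MCM4 (-0.62 ± 0.08) and CCNE2 (-0.60 ± 0.15) lower. The neuronal list had SYT1 higher and 2 genes lower, REST, a repressor of neuronal genes (-0.90 ± 0.14), and VGF (-0.62 ± 0.19). Stress genes had DNAJB9 (1.11 ± 0.10) and SLC7A11 (1.03 ± 0.07) higher and VEGFA (-0.88 ± 0.09) and CEBPB (-0.72 ± 0.08) lower. The cholesterol genes INSIG1 (-0.72 ± 0.15), FDFT1 (-0.60 ± 0.16) and PMVK (-0.39 ± 0.05) and the p53 targets GADD45A (-0.58 ± 0.04) and SESN1 (-0.42 ± 0.09) were lower. The androgen-repressed gene SI (1.90 ± 0.31) and the mesenchymal gene ACTA2 (1.27 ± 0.16) were the members of their lists with a region. Housekeeping genes had 3 lower, among them GAPDH (-1.10 ± 0.31) and ACTB (-0.72 ± 0.12), and 1 higher, YWHAZ (1.06 ± 0.13). Interferon response and HOX genes had 0 regions.

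The authors' deposited table listed 3703 H3K4me2 regions after knockdown, of which 2564 (69.2%, exact 95% interval 67.7 to 70.7) were higher and 1139 lower. Within 2 kb of a transcription start 43 of 936 regions rose (4.59%), against 2405 of 2634 elsewhere (91.3%), an odds ratio of 0.00458 with a p too small for double precision in Fisher's exact test. Lost regions had a median enrichment of 13.9 with siLUC and gained regions one of 0.90, and among regions matched on it the odds ratio for a rise at promoters was 0.292 (95% interval 0.139 to 0.613), against 0.164 with 20 equal-sized bins and 0.0315 when matched on the mean enrichment of both groups. The majority direction turned in the stricter sets, with 40.5% higher at an adjusted p of at most 0.001 and 42.6% among regions at or above the median mean.

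**Figure D3:**
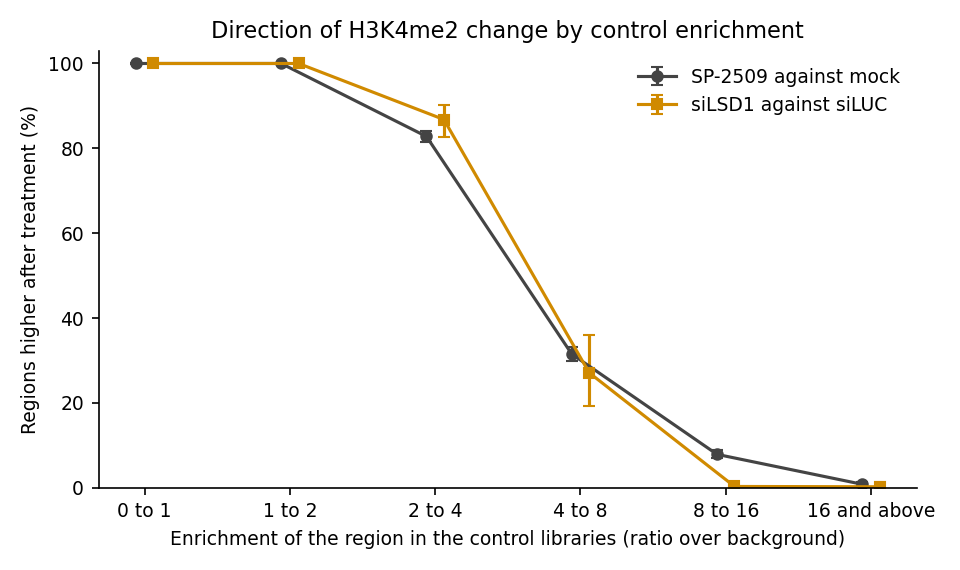
Share of called H3K4me2 regions that were higher after treatment (y axis, %) by the enrichment of the region in the control libraries (x axis, linear ratio over the authors' background), with exact 95% intervals for the counting of regions. The share runs from 100% below an enrichment of 2 to 0.827% (SP-2509) and 0.253% (siLSD1) at 16 and above.

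H3K9me2 after knockdown gave 57 called regions, 24 higher and 33 lower, and none of them reached an adjusted p of 0.05 in the authors' deposited table, where the smallest was 0.113. All 57 had an unadjusted p under 0.05 in that table. The 3 genes at this smallest value, named after their values were seen, were RMST, a long noncoding RNA of neural tissue (log2 ratio -1.15 ± 0.13), FAM190A (1.73 ± 0.36) and RMND1 (-1.57 ± 0.30). The RMST region on chromosome 12 from 97882601 to 97883700 averaged 24.1 ± 2.99 normalised reads after knockdown and 53.6 ± 0.849 with siLUC (SD, n = 2). None of the 14 lists had a gene with a region, and 1 region lay within 2 kb of a transcription start. The share of higher regions was 42.1% (exact 95% interval 29.1 to 55.9).

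H3K4me2 regions of SP-2509 and knockdown overlapped at 430 pairs, against a mean of 59.7 and a largest count of 87 over 1000 circular shifts (permutation p = 0.001, the smallest they can give). The shifts place regions anywhere on a chromosome, also where H3K4me2 is absent and no region could be called. They therefore cannot tell common targets of the treatments from common sites of the mark. In 298 pairs the mark fell in both, in 25 it rose in both, and in 107 it went opposite ways, so that 75.1% of pairs shared their direction (exact 95% interval 70.7 to 79.1). Most of these regions fell in each treatment, so many pairs would share their direction even if the treatments were unrelated. The odds ratio for a shared direction was 2.96 over all pairs (Fisher's exact test, p = 0.000362), but in a split chosen after seeing the data it was 1.32 at promoters (p = 0.560) and 0.550 elsewhere (p = 0.156). At the promoter of RBL2, a member of the retinoblastoma family, the log2 ratio was -0.87 ± 0.09 with SP-2509 and -0.51 ± 0.06 with siLSD1. KIAA0182 fell by 0.73 in both, the lactate transporter gene SLC16A1 by 0.70 and 0.68, and the ubiquitin-conjugating enzyme gene UBE2D3 by 0.22 and 0.53. A pericentromeric pair on chromosome 4 near 49164201 rose by 0.31 ± 0.06 with SP-2509 and fell by 0.16 with siLSD1.

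**Figure D4:**
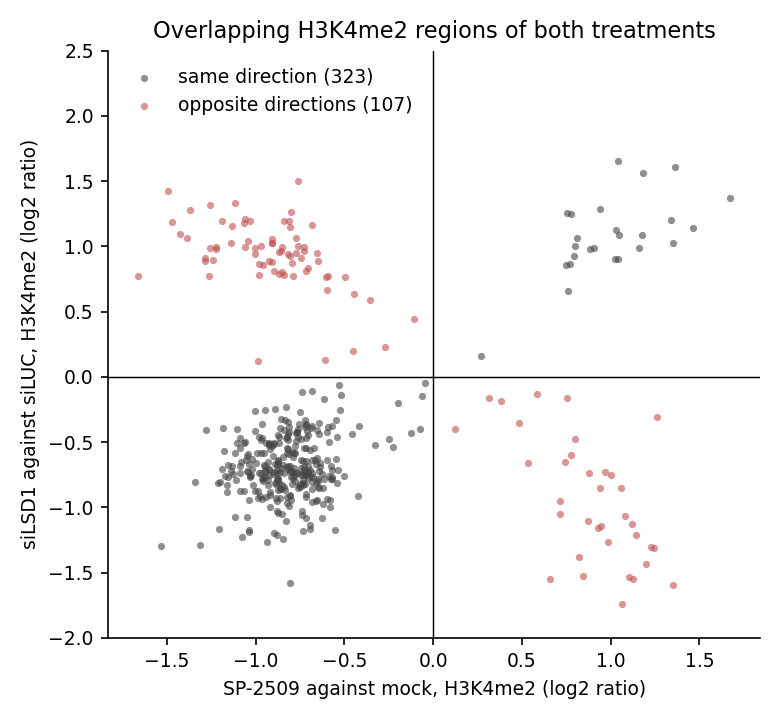
Log2 ratio of H3K4me2 after SP-2509 against mock (x axis) and after siLSD1 against siLUC (y axis) for the 430 overlapping pairs of regions, 1 point each. The 323 pairs in the same direction are grey, most of them (298) lower in both, and the 107 pairs in opposite directions are red.

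H3K4me2 and H3K9me2 regions of SP-2509 overlapped at 39 pairs, against a mean of 42.4 over the shifts (permutation p = 0.731), so the overlap was not above that of shifted regions. H3K9me2 rose in all 39, while H3K4me2 rose in 31 and fell in 8. In the body of LCMT1, a methyltransferase of protein phosphatase 2A, H3K9me2 rose (2.42 ± 0.65) and H3K4me2 fell (-0.77 ± 0.21), and the same held near TMEM100 (2.04 ± 0.11 and -0.84 ± 0.13). Near AIPL1 (1.80 ± 0.23 for H3K9me2 and 1.47 ± 0.48 for H3K4me2) and OVCA2 (1.36 ± 0.19 and 1.19 ± 0.17) both marks rose. The H3K9me2 regions of the treatments shared 0 pairs (shift mean 0.099), and the H3K4me2 and H3K9me2 regions of the knockdown shared 0 pairs (shift mean 0.12). With expected counts this low, an absence of overlap was not detectable as a departure from chance.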

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

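The tests on immunoprecipitation efficiency, on chance values of the controls, on promoter and other pairs, on the origin of the H3K9me2 gain and at the adjusted p limit of 0.001 were chosen after the results were seen.

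The balance of H3K4me2 gains and losses differed between the treatments, with an odds ratio of 0.663 for a higher region under SP-2509 against knockdown (Fisher's exact test, p = 5.23e-27, regions not independent), which turned to 2.65 at an adjusted p of at most 0.001. In both, promoters such as KDM5B under SP-2509 and CTBP1 under siLSD1 fell and regions of low control enrichment rose, the pattern a uniform drop in immunoprecipitation efficiency may give. Chance highs and lows of the control libraries stay open as well. Of pairs of a lost and a gained region, the lost one had the larger treated enrichment in 65.7% under SP-2509 (95% interval 64.4 to 67.1). Under knockdown it was 85.8% (83.5 to 87.8). These shares cannot decide, since no region below a control enrichment of 2 was called lower. Lost regions thus came from more strongly marked sites, which may have the larger treated enrichment under chance too. A uniform drop stays open as the whole cause in both treatments. In the knockdown, promoters rose less often than other regions of equal control enrichment (odds ratio 0.292, 95% interval 0.139 to 0.613, against 0.164 in the 20 equal-sized bins used first and 0.0315 at matched mean enrichment). That cannot decide, since direction nearly followed control enrichment, which was larger in the lost region in 99.7% of pairs. The odds ratio then rests on few promoters of intermediate enrichment, and no uniform drop was simulated. Under SP-2509, 2.05% (1.61 to 2.56) of the regions above the median enrichment of lost regions rose at an adjusted p of at most 0.01 in the authors' deposited table. These were 75 of the 17002 regions passing that limit, a number its false calls might reach, so they cannot decide either. Promoters rose more often at matched control enrichment under SP-2509 (odds ratio 3.44, 2.92 to 4.06) but only slightly so at matched mean enrichment (1.35, 1.20 to 1.52). LSD1 inhibition or depletion itself remains an untested explanation.

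H3K9me2 differed more, with an odds ratio of 546.661 for a higher region under SP-2509 against knockdown (Fisher's exact test, p = 1.40e-54), although none of the 57 knockdown regions passed an adjusted p of 0.05. The scaling between libraries stays open as a source of part of the rises at genes such as PGM1 and EHMT1: 100% of the higher regions also had more unscaled reads with SP-2509, but each called rise was at least 1.76-fold and the mean steps differed by 1.71-fold, so that outcome was nearly fixed. Signal shared with H3K4me2, from antibody cross-reaction or local openness, stays open. Only 1.11% of the higher H3K9me2 regions overlapped a higher H3K4me2 region, so few had a called gain of both marks. The tables list only called H3K4me2 changes, though, and openness was not measured. A difference in H3K9me2 immunoprecipitation between the treated and mock libraries, which the design does not separate from the compound, was not tested and might contribute, as might LSD1 inhibition.

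At 107 overlapping pairs H3K4me2 moved opposite ways in the treatments, a difference that was not tested as an interaction. Every library lay on its own side at these pairs, as at 99.9% of all called H3K4me2 regions of either treatment. Selection of the regions on these same libraries nearly fixed that outcome. H3K4me2 fell with SP-2509 and rose with siLSD1 in 72 pairs, among them, chosen after their values were seen, SYNJ2BP (-1.19 ± 0.35 and 1.19 ± 0.08) and PTPRM (-0.77 ± 0.25 and 0.95 ± 0.14), and did the reverse in 35, such as GAS1 (0.88 ± 0.32 and -0.73 ± 0.11) and TRAF3IP2 (0.80 ± 0.12 and -0.48 ± 0.06). The TRAF3IP2 regions shared only positions 111926001 to 111926200, with control enrichments of 2.86 in mock and 11.04 with siLUC. The excess of shared directions over all 430 pairs (odds ratio 2.96) may follow from a common dependence on control enrichment, and the odds ratio of 0.0356 within 5 bins of it cannot decide, since direction nearly followed each comparison's own enrichment and the bins then favour opposite directions. The odds ratio was 1.32 at promoters (Fisher's exact test, p = 0.560) and 0.550 elsewhere (p = 0.156). Pairs lower in both had a median enrichment of 19.4 in mock and 13.2 with siLUC, against 5.67 and 2.08 in pairs lower with SP-2509 and higher with siLSD1, so the tables do not separate a shared LSD1 effect from that dependence.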

How the results depend on the processing

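The adjusted p limit of 0.05, the deposited X and Y annotation and the alternatives for the difference in direction were chosen after seeing the data. Across all results and alternatives other than leaving out a library, 91 values stayed the same (gene lists by their number only), 24 moved, 2 were weaker and 4 reversed, and the cause was not tested except where fewer regions follow from the limit itself. The share of higher H3K4me2 regions reversed with a larger group mean at or above the table's median (37.6% for SP-2509, 42.6% for siLSD1) and, for siLSD1, at an adjusted p of at most 0.001 (40.5%). For SP-2509 it was 61.7% at 0.01, 64.3% at 0.001, 60.8% at 0.05, 84.6% with an absolute log2 ratio of at least 1 and 58.1% from the enrichment, and for siLSD1 70.9% at 0.01 and 93.0% with that log2 ratio. The H3K9me2 share for SP-2509 was 100% at 0.001, 99.9% above the median mean and 99.4% from the enrichment. Region counts for H3K4me2 fell to 7496 (SP-2509) and 2280 (siLSD1) with that log2 ratio, to 8942 and 1852 above the median mean, and to 575 for siLSD1 at 0.001. For H3K9me2 they fell to 1395 (SP-2509) and 29 (siLSD1) above the median mean, to 364 for SP-2509 at 0.001, and to 0 for siLSD1 at 0.05, 0.01 and 0.001. The gene lists passing for SP-2509 H3K4me2 stayed at 1 with promoter regions only, where neuronal genes (adjusted p = 0.00396, exact test) took the place of the methylation enzymes, and went to 0 at 0.001 and to 3 with genes whose regions all go one way, where neuronal genes and stress genes joined the methylation enzymes. Pairs of H3K4me2 and H3K9me2 regions under SP-2509 fell to 7 above the median mean, where the shifts also gave fewer. The methylation enzymes lost their call with promoter regions only (7.14% higher, odds ratio 0.236) and at 0.001 (18.8% higher, odds ratio 0.217), with fewer genes. Leaving out each library in turn left the share of higher regions at 59.9% and 69.2% for H3K4me2 and at 99.7% and 42.1% for H3K9me2 (SP-2509 and siLSD1), which says nothing about stability, since the regions were selected with all libraries and 99.86% or more were separated. The promoter odds ratio kept its direction with promoters within 1 or 5 kb (0.0759 to 0.171 for SP-2509, 0.00188 to 0.00874 for siLSD1). Matching on enrichment is not in the counts above. It turned the odds ratio for SP-2509 (3.44 on control and 1.35 on mean enrichment) but not for siLSD1 (0.292 and 0.0315). The difference in direction for H3K4me2 reversed at an adjusted p of at most 0.001 (odds ratio 2.65) and was 0.411 to 0.811 in the other 5 alternatives. For siLSD1 H3K9me2 promoters within 1 kb gave no value. The authors' test was not rerun without a library. No paired analysis was possible because the library values in the tables carry no replicate numbers. With 14 reads in the median H3K9me2 region of a mock library, low signal and low depth are not separated.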

Other observations

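All tests and genes here were chosen after the results were seen, and no explanation was tested for them. Some long genes gained H3K4me2 at many separate regions under SP-2509. PPFIA2, a scaffold of synapses, had 27 regions covering 80.9 kb between 81770601 and 82017300 on chromosome 12, all 27 higher, with a median log2 ratio of 1.24. The noncoding LINC00478 on chromosome 21 had 29 regions, 27 of them higher, and NAALADL2 on chromosome 3 had 16, all higher, with a median of 1.01. FOLH1, in the luminal list, had 10 regions within 39.3 kb, 9 of them higher. After knockdown LINC00478 had 6 regions, LRBA 6 and ZBTB20 6, and all of these were higher. So were 92.4% of all gene-body regions after knockdown, against 67.1% under SP-2509. FOXP1, by contrast, had 7 higher and 5 lower regions under SP-2509.

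Genes called in both H3K4me2 comparisons numbered 1158, of which 301 were higher in both and 274 lower in both, while 217 were higher with SP-2509 and lower with siLSD1 and 366 the reverse. The odds ratio of a shared direction over these genes was 1.04 (Fisher's exact test, p = 0.765). Under SP-2509, 660 genes had a region of each mark. H3K9me2 was higher with higher H3K4me2 in 454 of them and with lower H3K4me2 in 205, among them KDM4C, EHMT1, SMYD3, VEGFA and ZBTB16.

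Chromosome X held 215 of 2790 H3K9me2 regions under SP-2509 (7.71%, exact 95% interval 6.74 to 8.76) but 538 of 17884 H3K4me2 regions (3.01%), an odds ratio of 2.69 (Fisher's exact test, p = 2.15e-28, regions not independent), and 213 of the 215 were higher. The 7 H3K9me2 losses under SP-2509 included ACAP2 (-1.74 ± 0.55), ICA1L (-1.43 ± 0.50) and EXOC6B (-1.97 ± 0.17), and EXOC6B also had 3 gained regions.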
